A study of Mus musculus with 2 samples.

How the data were processed

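The sources used here are the sample labels, the deposited quantification tables and transcript models of 2 libraries, and the GENCODE M21 annotation of the mm10 assembly. The counts are raw reads per transcript model, made by the authors before deposition with an annotation-based long-read tool, which the file headers of the models name as TALON, and with each library processed separately. The aligner, the read correction and the software versions are not given in the sources used here. The labels carry the same donor identifier for both libraries, an RNA input of 3 µg and 2 µg, and a sex entry of not collected beside a description that says male. The tests compare the 2 libraries, not conditions.

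Reads of spike-in controls were left out of all totals. Reads were summed per annotated gene over all model classes and divided by the library's mouse reads to give CPM. Unannotated models of the libraries were matched by gene and intron chain. The reads carry no molecular identifiers and came through PCR, so intervals and counting errors cover counting alone. The floor was 3 reads, which is 1.05 CPM in replicate 1 and 0.997 CPM in replicate 2. Genes that share reads with overlapping genes or with copies elsewhere are uncertain.

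Gene differences were tested by the two-sided exact binomial test for genes with at least 10 reads over both libraries, and log2 ratios used a pseudocount of 1 CPM. Isoform use was taken from annotated, NIC and NNC models, with at least 5 reads in each library for an unannotated model and at least 20 isoform reads per gene and library. Leading isoforms and cassette exons were tested by the two-sided Fisher exact test. A cassette exon is one that some annotated transcript includes and another skips with the same outer splice sites, and its inclusion was read from adjoining splice junctions. P values were adjusted by the Benjamini-Hochberg method over all tested genes or exons, at 0.05, and for lists also over the list alone. The median log2 ratio of each list was ranked among 10000 random lists drawn from 20 bins of expression, and called outside the percentiles 2.5 to 97.5. Transcript length is the read-weighted annotated length. Lists, tests, limits and the first set of alternatives were fixed before the data were examined.

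Genes were named by rule: the 20 highest nuclear protein-coding genes, the 3 highest of each list, the 10 largest called log2 ratios in each direction among genes with at least 50 reads, the 20 most read genes of the isoform list, the 10 most read genes with a second isoform at 30% or more, the 10 largest called differences in leading share, the 10 unannotated leading models with the most reads in the library where each had fewer, the 20 most read list exons at 5 to 95% inclusion and the 5 most different exons outside the list. Other genes are named to show what a list holds.

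In a self-test, counts were simulated from the libraries with 100 changed genes or exons per setting. The binomial test found 44 of 100 genes changed 2-fold and 89 changed 4-fold, with 4 false calls. The isoform test found 52 at a change of 20 percentage points and 93 at 40, with 1 false call, and the exon test 68 and 96, with 0. All 100 lists shifted by 1 log2 unit were found, and 6 of 100 unshifted lists were called. The simulated counts held counting noise alone, and the lists held unrelated random values. Among well-read genes the libraries had a log2 spread of 0.47 where counting alone gives 0.08. The false calls of the self-test therefore do not carry over to these libraries.

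Alternatives changed the read minimum, the pseudocount, the scaling, the model classes, the size of the difference and the error model, and left out each replicate in turn. Centring on transcript length, leaving out exons shorter than 19 nt, and leaving out models that differ from an annotated chain by a very short exon or intron were chosen after seeing the data, as were the grouping of isoforms by protein form, the second choroid plexus list and the exons that no annotated transcript skips. Grouping by protein form used annotated protein sequences, with P values adjusted over its 8 tests alone. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. DESeq2 gave scaling factors alone, and edgeR gave scaling factors and the exact negative binomial test with an assumed variation. Transcript ends, polyadenylation sites, alleles and spike-in dose were not analysed here. Igf2, Dynlrb2, Eomes, Mki67 and Xist were not analysed here, and results of some genes that the rule names are not reported here.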

Results

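Long-read RNA sequencing, in which a read covers most or all of an RNA molecule, was used to describe the transcripts of the mouse hippocampus at 6 months of age. The tissue is labelled as male C57BL/6 (strain B6NCrl), and the labels name MODEL-AD, a consortium that makes mouse models of Alzheimer's disease, as its source. The series holds 1 group of 2 libraries, labelled biological replicates, made from 3 µg of RNA (replicate 1) and 2 µg of RNA (replicate 2). No treatment, genotype or age was compared, so each comparison is between genes, isoforms or exons, or between the 2 libraries. Replicate 1 had 2858381 reads on mouse transcript models and replicate 2 had 3009935. Annotated genes with at least 1 read numbered 18652 and 18668, and 16598 of the 20722 had reads in both. Both libraries carry the same donor label, and the labels do not say whether they came from different animals. SDs therefore measure the spread between these libraries, which may be technical. The tests set each difference against counting noise alone.

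Annotated models and protein-coding genes each held most of the reads. Annotated models took 70.4% of the reads in replicate 1 (exact 95% interval 70.3 to 70.4) and 75.8% in replicate 2 (75.7 to 75.8), a mean of 73.1% ± 3.84 (SD, n = 2). Protein-coding genes held 94.7% and 96.0% of the reads. Spliced models outside the annotation were of 2 classes, NIC, which joins annotated splice sites in an unannotated way, and NNC, which uses at least 1 unannotated splice site. NIC models took 6.81% and 6.79% of the reads, and NNC models took 3.69% in each library. With only models of at least 2 reads, the mean shares were 6.04% for NIC, 2.43% for NNC and 76.5% for annotated models. ISM, genomic and antisense models had larger shares in replicate 1. ISM models, which match part of an annotated splice chain, took 10.4% (10.3 to 10.4) against 7.91% (7.88 to 7.94), genomic models, which lie in a gene without matching its splicing, 4.73% against 3.17%, and antisense models 3.67% against 2.38%. Reads of the mitochondrial genome were few, 0.0864% (0.0830 to 0.0899) in replicate 1 and 0.0474% (0.0450 to 0.0499) in replicate 2. Of 77237 distinct NIC splice chains, 22.8% had reads in both libraries, and these held 76.6% and 75.9% of the NIC reads. Of 91598 NNC chains, 11.4% had reads in both, with 48.8% of the NNC reads in each library.

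**Figure D1:**
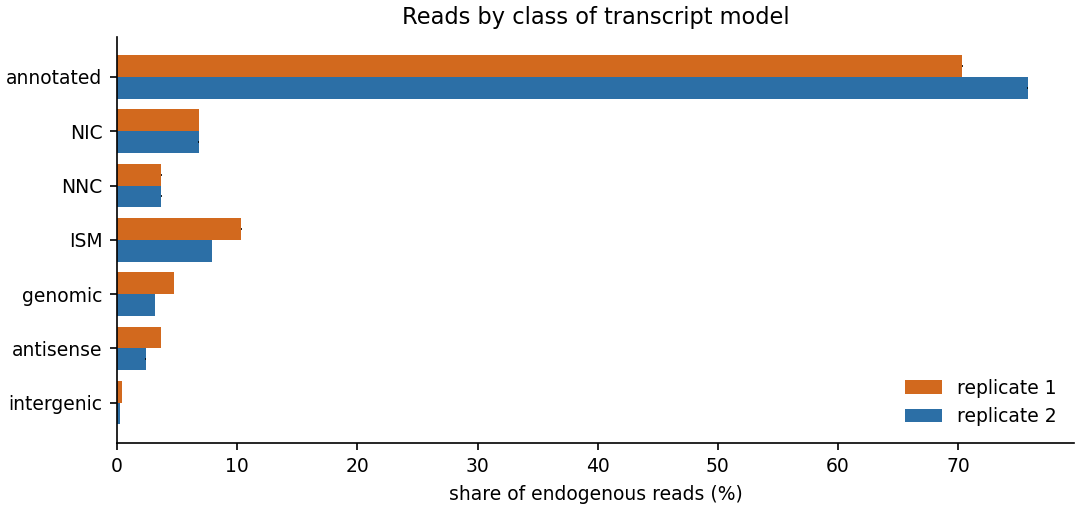
Share of mouse reads (%, horizontal axis) on each class of transcript model in replicate 1 (orange) and replicate 2 (blue), with exact 95% intervals that are mostly narrower than the line. Annotated models took 70.4% and 75.8% of the reads, and ISM, genomic and antisense models took a larger share in replicate 1.

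The gene with the most reads was Hspa8, a constitutive chaperone of the HSP70 family, with 14731 ± 2796 CPM (reads scaled to the library total; SD, n = 2). It was followed by Mbp, a structural protein of myelin (7225 ± 2171 CPM), Cpe, an enzyme that trims neuropeptide precursors (6794 ± 1101 CPM), Snap25, a protein of synaptic vesicle fusion (5430 ± 2105 CPM), and Trf, transferrin, made in the brain by oligodendrocytes (5194 ± 1810 CPM). Next came the glycolytic enzyme Pkm (5079 ± 858 CPM), the sodium pump subunit Atp1b1 (4713 ± 262 CPM), the neurofilament Nefl (4216 ± 152 CPM) and the secreted astrocyte protein Sparcl1 (3959 ± 592 CPM). The other members of the 20 highest nuclear protein-coding genes were Tubb2a, Ckb, Ndrg4, Tuba1a, Aldoc, Gpm6a, Itm2b, Ywhae, Atp5a1, Ywhah and Ppp3ca. Aldoc, an aldolase of astrocytes, was nearly equal in the libraries (2621 ± 32.3 CPM). Ckb, the brain creatine kinase, had 1544 CPM in replicate 1 and 4901 in replicate 2, and Ppp3ca, a catalytic subunit of calcineurin, had 3556 and 1190. On the mm10 assembly Hspa8 (ENSMUSG00000015656.17) lies on chromosome 9 from 40800984 to 40810087, Mbp (ENSMUSG00000041607.17) on chromosome 18 from 82475146 to 82585637, and Snap25 (ENSMUSG00000027273.13) on chromosome 2 from 136713453 to 136782428.

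Markers of each hippocampal field and cell class were read. Summed over each list, markers of CA1 pyramidal neurons reached 523 ± 12.8 CPM (SD, n = 2 for each list), led by Mpped1, Wfs1 and Fibcd1, those of CA2 250.4 ± 12.5 (Necab2, Amigo2, Rgs14), those of CA3 331 ± 64.3 (Bok, Homer3, Cpne4) and those of dentate granule cells 326 ± 104 (C1ql2, Plk5, Prox1). General markers of excitatory neurons summed to 2871 ± 55.4 CPM (Chn1, Neurod6, Itpka) and those of interneurons to 865 ± 10.2, most of it Gad1, an enzyme of GABA synthesis (687 ± 13.5), with Gad2 and Lhx6 next. Glial sums were 16749 ± 1582 CPM for oligodendrocytes (Mbp, Trf), 5541 ± 195 for astrocytes (Aldoc, Gja1, Slc1a3), 856 ± 67.3 for microglia (P2ry12, Csf1r) and 65.5 ± 10.8 for oligodendrocyte precursors (Pdgfra, Neu4, Gpr17). Vessels gave 556 ± 106 CPM for endothelium (Cldn5, Itm2a, Slco1a4) and 186 ± 67.2 for mural cells (Rgs5, Vtn, Acta2). Meningeal fibroblast markers reached 210.4 ± 28.5 CPM (Ptgds, Dcn, Slc6a13), blood 14.4 ± 3.42 (Alas2, Hba-a1, Hba-a2), ependyma 9.26 ± 3.23 (Tekt1, Rsph1, Foxj1) and perivascular immune cells 7.68 ± 0.521 (F13a1, H2-Ab1, Mrc1). Markers of neighbouring regions were also present, at 150.1 ± 33.2 CPM for cortex and subiculum (Fezf2, Rprm, Tshz2), 179 ± 102 for thalamus (Slc17a6, Calb2, Prkcd) and 170.1 ± 1.39 for striatum (Ppp1r1b, Penk). The striatum list ranged from Ppp1r1b (284 and 264 reads) down to Adora2a (3 and 6), Drd2 (1 and 8) and Drd1 (0 and 7). These sums alone do not show that tissue of those regions was included. Choroid plexus markers, led by Enpp2, Ttr and Prlr, summed to 4563 CPM in replicate 1 and 475 in replicate 2 (2519 ± 2891). Whether RNAs of all lengths were recovered alike within a library was not tested. Among interneuron markers, Sst (721 nt) had 5 and 8 reads and Npy (566 nt) 4 and 11, but Slc32a1 (2797 nt) also had 0 and 2. The sums therefore do not rank cell classes by abundance.

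Functional groups spanned a similar range. Genes of synaptic vesicle release summed to 10031 ± 1412 CPM (Snap25, Syn2, Cplx1), postsynaptic genes to 4766 ± 52.1 (Gria2, Camk2b, Nsf), nuclear genes of oxidative phosphorylation to 5932 ± 837 (Atp5a1, Atp5b, Uqcrc1) and heat shock genes to 16034 ± 2822, most of it Hspa8, with Hsph1 and Hsp90aa1 next. Immediate early genes, which are switched on by neuronal activity, summed to 994 ± 172 CPM, led by Junb (436 ± 62.4), Egr4 (153 ± 5.83) and Dusp1 (112 ± 72.8). Markers of newborn neurons and dividing cells were low at 82.1 ± 50.3 CPM, most of it Calb2 and Neurod1, while Dcx, a protein of migrating young neurons, had 9 and 7 reads. Long non-coding RNAs summed to 429 ± 11.6 CPM (Meg3, Snhg11, Malat1). Genes tied to Alzheimer's disease summed to 5163 ± 1949 CPM, led by Apoe (1847 ± 1504), App (1513 ± 159) and Clu (582 ± 47.2). The Y-linked genes Ddx3y (188 and 180 reads), Eif2s3y (136 and 159), Uty (19 and 33) and Kdm5d (17 and 17) were read in both libraries, and their list summed to 128 ± 2.33 CPM.

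The libraries resembled each other across genes but differed by more than counting noise. Over 20722 genes, log2(CPM + 1) gave Pearson's r = 0.960 and Spearman's rho = 0.933 across genes, which are not independent replicates. Of 13576 genes with at least 10 reads, 4855 (35.8%) differed by the two-sided exact binomial test with Benjamini-Hochberg adjustment below 0.05, 2520 higher in replicate 2 and 2335 higher in replicate 1, and 1790 of them differed at least 2-fold as well. The test compares these libraries, not conditions. Among 2426 genes with at least 500 reads, the log2 ratio had a spread of 0.47 where counting alone gives 0.08, and 91.2% of these genes lay within 2-fold. With an assumed biological coefficient of variation of 0.1, 2338 genes were called. This value was not estimated from these libraries, and it allows for less than the spread of 0.47 seen between them.

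**Figure D2:**
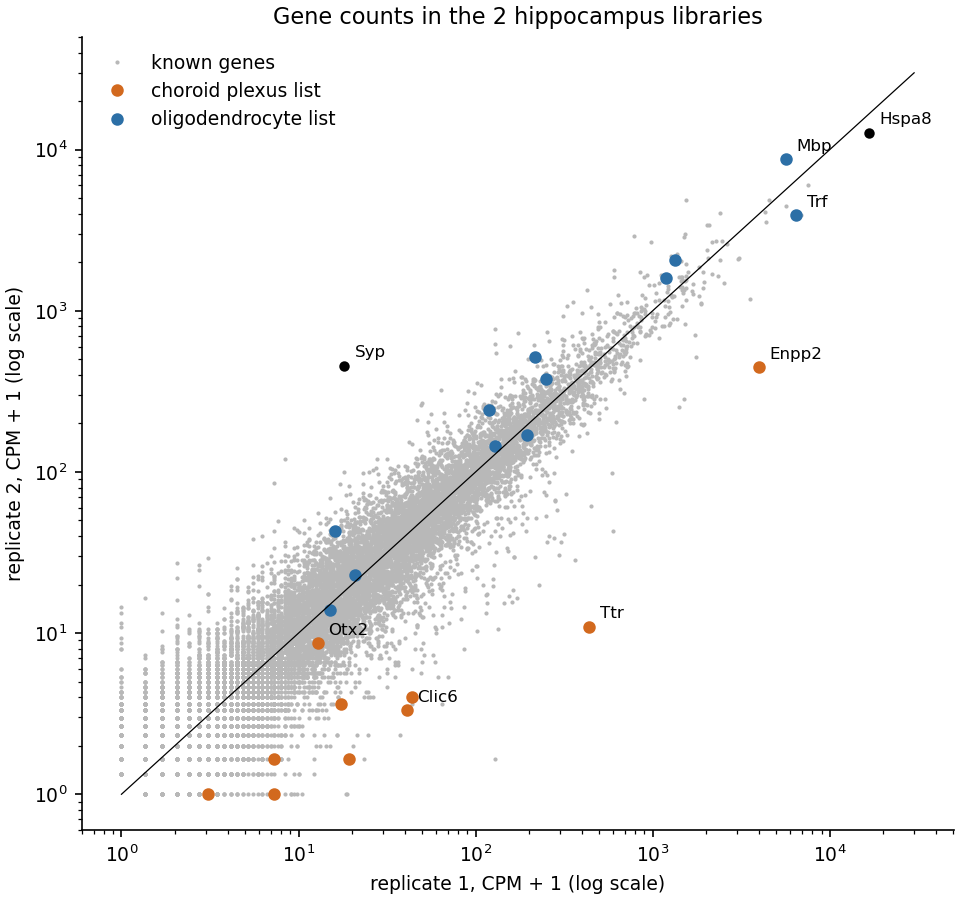
CPM + 1 of each annotated gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales, with the line of equal values, choroid plexus markers in orange and oligodendrocyte markers in blue. Most genes lie near the line, while Ttr, Enpp2 and Clic6 lie far below it and Syp above it.

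Among the genes higher in replicate 1, those of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were among the most different. Ttr, the thyroid hormone carrier of that fluid, had 1250 reads against 30, a log2 ratio of CPM + 1, replicate 2 over replicate 1, of -5.32 (counting error 0.27), and Kcnj13, a potassium channel of that epithelium, had 182 against 8 (-4.14, counting error 0.52; exact binomial adjusted p = 2.79e-44). Enpp2, which makes lysophosphatidic acid, had 11381 against 1348. Other genes of the 10 most different in this direction were Ptpra, a receptor phosphatase (1699 against 127 reads, log2 ratio -3.78, counting error 0.13), Ppm1b (1044 against 83), Tmem165 (196 against 13) and Actr5 (104 against 4). Klhl10 (363 against 2), Gm20521 (51 against 0), Gm20431 (50 against 0) and Gm49327 (64 against 2) are uncertain, because other models at the same place took reads. For Klhl10 these were 305 reads of an unannotated locus in replicate 2, and Gm49327 overlaps Gm49329, which had 3 and 79 reads.

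Among the genes higher in replicate 2, Syp had the largest ratio. Syp, a membrane protein of synaptic vesicles on chromosome X (7638471 to 7653256), had 49 reads in replicate 1 and 1369 in replicate 2, a 25.1-fold ratio of CPM + 1, the scale of all folds here (log2 4.65, counting error 0.21). Lmo3, a transcriptional cofactor, had 21 and 359 reads (log2 ratio 3.85, counting error 0.32; exact binomial adjusted p = 7.43e-75), Rtn4rl1, a Nogo receptor homologue, 18 and 253, and Id2, an inhibitor of basic helix-loop-helix factors, 13 and 112. Adcyap1, which encodes the neuropeptide PACAP, had 5 and 71 reads, Ackr3 5 and 56, Brsk2 5 and 77, Lpcat4 6 and 85, and Tmem161b 3 and 63. Gm49329 was the remaining gene of these 10. Annotated models held 9 and 1211 of the Syp reads, and 0 and 3 of the Brsk2 reads. The Brsk2 difference therefore rests almost wholly on other model classes and is uncertain. Syp stood apart from its list, in which Snap25 was 1.75-fold higher in replicate 1 and Cplx1 1.58-fold higher in replicate 2.

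Of the 27 gene lists with enough members to rank, 4 stood outside the central 95% of 10000 random lists matched on expression. The ranks were not adjusted for the number of lists. In the self-test 6 of 100 unshifted lists were called, so a list can fall outside without a shift. The choroid plexus list had a median log2 ratio of -3.15, below every random list (percentile 0), with 8 of 9 tested members higher in replicate 1, among them Prlr (123 against 9 reads), Clic6 (114 against 7) and Kcne2 (52 against 2). Otx2 did not pass the test (34 against 23 reads). Oligodendrocyte markers had a median of 0.51 (percentile 99.5), with 7 members higher in replicate 2, such as Mobp (2.38-fold) and Mbp (1.54-fold), 1 higher in replicate 1 (Trf, 1.65-fold) and 4 not called. Genes of oxidative phosphorylation had a median of 0.40 (percentile 98.4), with 9 of 15 higher in replicate 2, such as Uqcrfs1 (2.26-fold) and Cox4i1 (1.83-fold), and none higher in replicate 1. Cortex and subiculum markers had a median of -0.62 (percentile 0.94), with Fezf2, Fn1 and Rorb higher in replicate 1 and 5 not called. Genes with short transcripts were higher in replicate 2, with a median log2 ratio of 0.60 in the tenth of genes with the shortest transcripts and -0.19 in the tenth with the longest. After centring on genes of like length, a step chosen after the data were seen, the oxidative phosphorylation median was 0.30 (percentile 97.2). The cortex and subiculum median was then -0.58 (percentile 2.7). Both lay inside the random range, but close to its limits.

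The remaining lists lay inside the random range. Members higher in replicate 2 and in replicate 1 numbered 1 and 2 for CA1, 1 and 1 for CA2, 2 and 1 for CA3, 2 and 0 for dentate granule cells, 2 and 2 for excitatory neurons, 2 and 1 for interneurons, 4 and 2 for astrocytes, 3 and 2 for microglia, 0 and 1 for oligodendrocyte precursors, 1 and 0 for endothelium, 3 and 0 for mural cells, 2 and 1 for meningeal fibroblasts, 2 and 0 for thalamus and 2 and 1 for striatum. The 2 thalamus markers were Slc17a6, the vesicular glutamate transporter VGLUT2 (63 and 292 reads), and Calb2, calretinin (63 and 252). The thalamus median of 0.61 rose to 1.12, outside the random range, with members of at least 50 reads only. No member was called in the blood, sex-linked, ependymal or perivascular lists, and the last 2 had too few tested members for a rank. Among functional lists the numbers were 5 and 6 for synaptic vesicles, 2 and 5 for postsynaptic genes, 3 and 2 for heat shock, 0 and 4 for immediate early genes (Junb, Dusp1, Fos and Egr2), 2 and 0 for newborn neurons, 1 and 1 for long non-coding RNAs and 6 and 1 for genes tied to Alzheimer's disease. Apoe, the lipid carrier of astrocytes, was 3.71-fold higher in replicate 2, while Sorl1 was 1.41-fold higher in replicate 1. Adjusted over the list alone, the counts were the same except for CA2 (2 and 2), interneurons (2 and 2), microglia (5 and 2), ependyma (0 and 1), cortex and subiculum (1 and 5), oligodendrocytes (7 and 2), oxidative phosphorylation (10 and 0) and postsynaptic genes (3 and 5). RNA input also differed, with 1 library at each amount, and no list shift was compared with it.

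**Figure D3:**
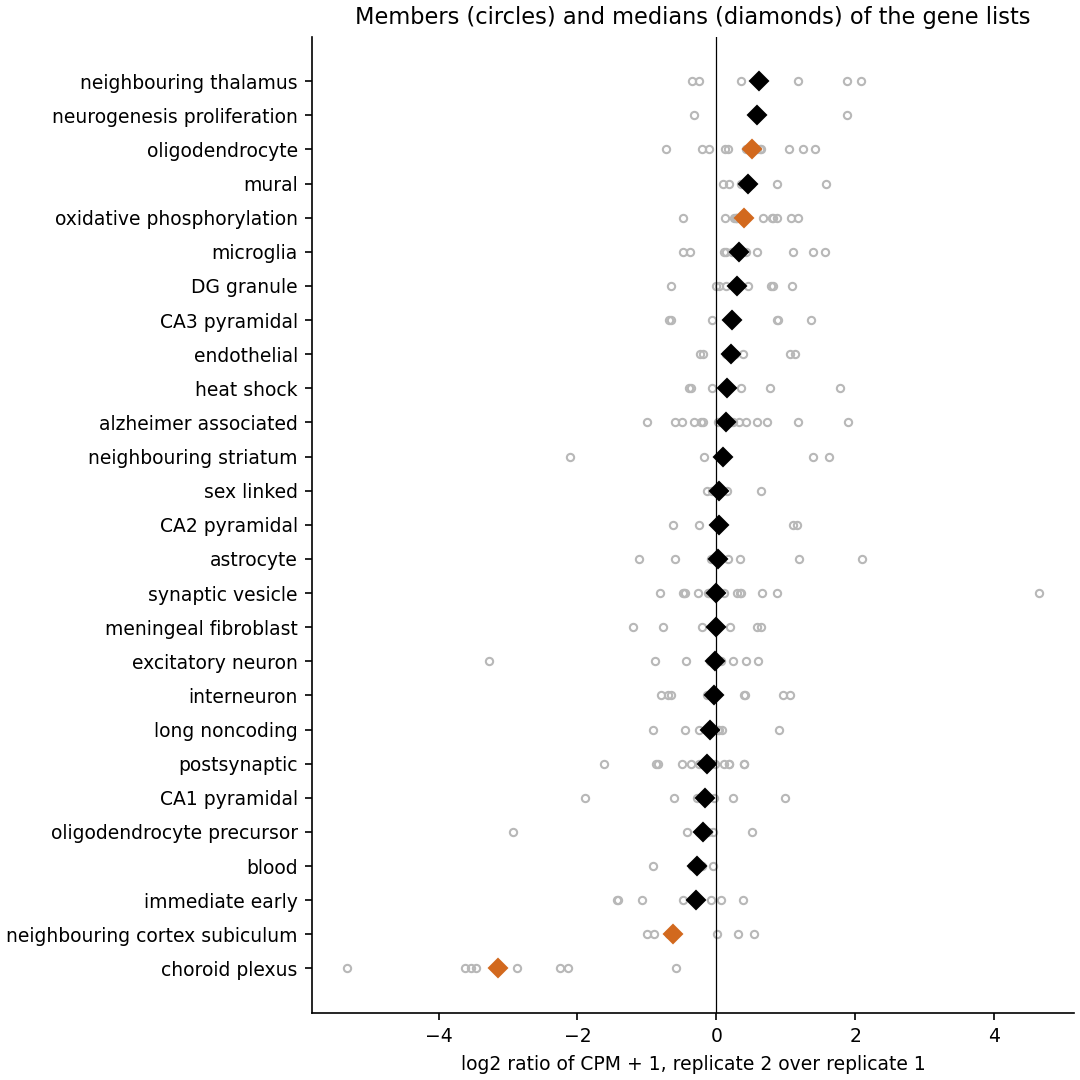
Log2 ratio of CPM + 1, replicate 2 over replicate 1 (horizontal axis), of each list's tested members (circles) and their median (diamonds), with medians outside the central 95% of matched random lists in orange. The choroid plexus list lies at -3.15 and the other medians between -0.62 and 0.61.

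Genes fixed for their known splicing differed in how their reads were shared among isoforms. Mbp-211, which encodes 128 amino acids, took 72.5% and 74.6% of the isoform reads of Mbp in replicates 1 and 2, and Mbp-212, of 169 amino acids, 16.2% and 15.3%. The glutamate receptor genes Gria2 (Gria2-201 60.1% and 63.9%, Gria2-202 33.5% and 31.1%) and Gria1 (Gria1-202 66.6% and 69.5%, Gria1-201 28.3% and 25.6%) each used 2 main forms of equal protein length. Syn2, a synapsin, was led by Syn2-205 (57.7% and 62.9%), followed by Syn2-201 (40.4% and 36.0%). App was led by App-201, of 695 amino acids (91.1% and 93.6%), Apoe by Apoe-206 (96.4% and 97.8%), Snap25 by Snap25-201 (89.8% and 92.9%), and Gfap, the astrocyte filament, by Gfap-201 (84.9% and 87.8%). Pkm-202 (83.8% and 88.5%), Ndrg4-202 (76.1% and 78.9%), Ndrg2-202 (55.5% and 54.7%) and Camk2b-209 (1092 of 1369 and 1625 of 2168 reads, Fisher exact adjusted p = 0.0419) also led their genes.

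Across 7077 genes with at least 20 isoform reads in each library, the leading isoform had a median share of 92.8% in replicate 1 and 93.3% in replicate 2, and it was the same in both libraries in 6739 (95.2%). The second isoform reached 10% in both libraries in 2478 genes (35.0%), and 30% in 549. The most read of these 549 were Hspa5 (Hspa5-201 63.6% and 64.9%), Tcf25 (Tcf25-202 44.3% and 46.0%), Gria2, Eif4h (Eif4h-205 61.6% and 60.9%), Zcchc18 (Zcchc18-203 50.2% and 50.5%), Syn2, Scg2, Hmgcs1, Rpn2 and Nars. Of 60 genes fixed for their known splicing, 45 passed the read minimum, and in 36 the second isoform reached 10%.

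**Figure D4:**
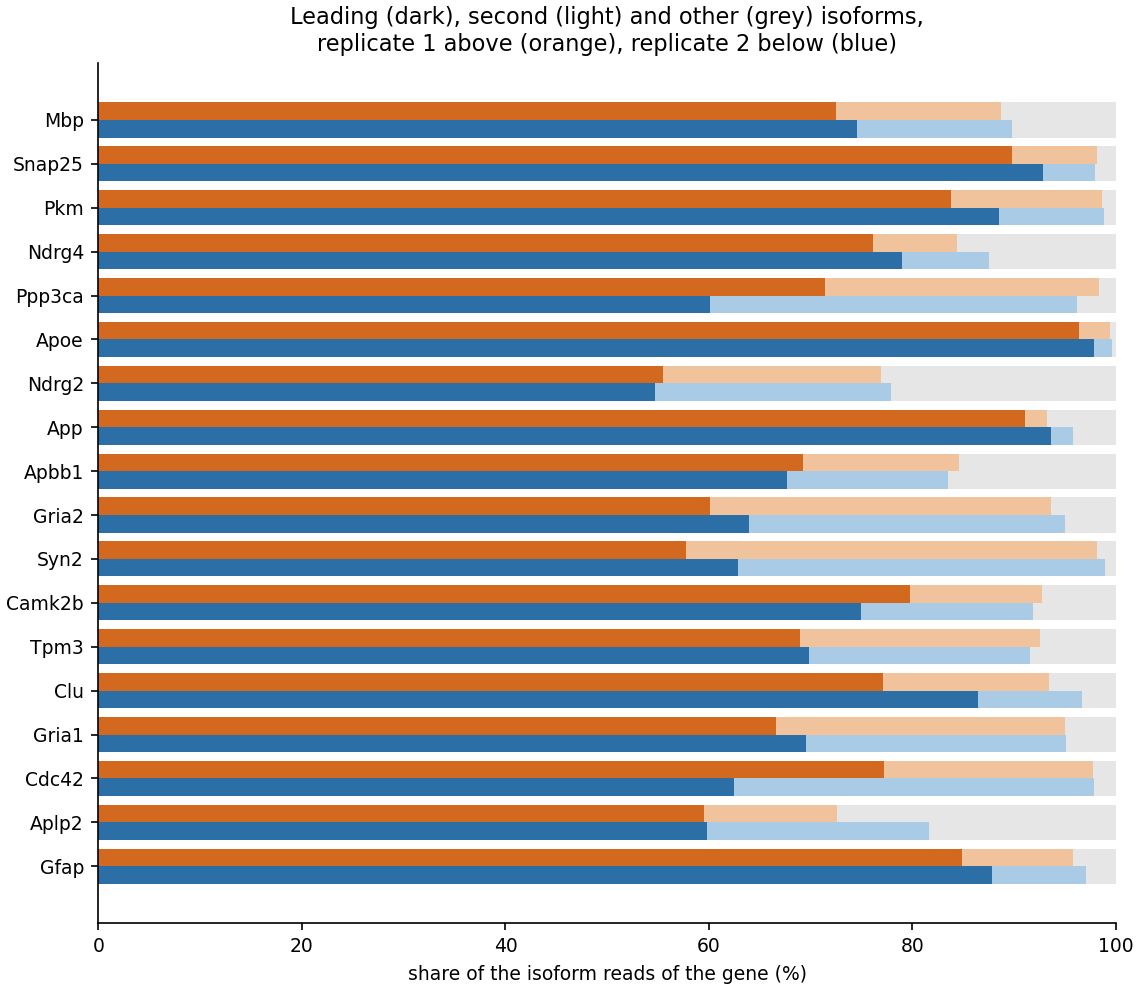
Share of each gene's isoform reads (%, horizontal axis) held by the leading isoform (dark), the second (light) and all others (grey), for the most read genes of the isoform list, replicate 1 in orange above replicate 2 in blue. Mbp-211 held 72.5% and 74.6%, and Cdc42-202 held 77.2% and 62.5%.

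The two-sided Fisher exact test of the leading isoform called 163 of 7077 genes (2.30%) after adjustment, 105 of them with a difference of at least 10 percentage points, and 379 were called when ISM models were included. In the isoform list 14 genes were called, and 18 when adjusted over the list alone. Cdc42-202 took 77.2% in replicate 1 and 62.5% in replicate 2 (Fisher exact adjusted p = 1.97e-11), Ppp3ca-201 71.4% and 60.1% (1.41e-28) and Clu-201 77.1% and 86.4% (3.92e-08). The largest difference was in Car12, a carbonic anhydrase, where Car12-202 took 39.4% (exact 95% interval 32.3 to 47.0) and 93.6% (87.3 to 97.4) of 180 and 110 reads. The others of the 10 largest were Gas2, Ajm1, Btbd11, Slc35f3, Cox19, Coq10a, Ppp2r2d, Sphkap and Pank1, and these had between 21 and 140 isoform reads per library.

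In 348 genes (4.92%) the same unannotated model led in both libraries, 264 of them NIC and 84 NNC, and in 1 library alone the count was 499 (replicate 1) or 544 (replicate 2). In Apbb1, which encodes an adaptor of the amyloid precursor protein, a NIC model held 69.3% and 67.6% of the isoform reads with a first intron from 105574417 to 105581134 on chromosome 7. Tpm3, a tropomyosin, was led by a NIC model (69.0% and 69.9%), as were Aplp2 (59.5% and 59.8%), Pls3 (76.0% and 75.4%) and Rpn2 (58.1% and 60.5%). Sept7, a septin, was led by a model that skips an annotated exon of 5 nt (89.4% and 93.3%), and Hnrnpk by an NNC model whose intron spans an annotated exon of 16 nt (42.6% and 38.0%). Oaz1 and Oaz2, the antizymes of polyamine metabolism, were led by models that retain an annotated intron of 1 nt (97.7% and 97.9%, 94.5% and 93.7%). With Cct6a and Chmp1a, all of these but Aplp2 were the 10 models with the most reads in the library where each had fewer. All introns were annotated in 202 of the 348, and 54 differed from an annotated chain by 1 skipped exon.

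Camk2b, a kinase of the postsynapse, included an exon of 45 nt in 86.7% and 81.1% of informative reads (exact adjusted p = 0.00108), and Camk2g included exons of 33 nt in 89.6% and 88.7%, of 63 nt in 59.7% and 52.3% (exact adjusted p = 0.0331), of 114 nt in 39.7% and 36.0% and of 69 nt in 35.9% and 27.5% (exact adjusted p = 0.0205). Mbp included its exons of 78 nt (chromosome 18, 82561778 to 82561855) in 9.46% and 8.56% and of 123 nt in 18.3% and 17.0%. Cadm1, an adhesion protein, included exons of 33, 54 and 84 nt in 10.6% to 23.3%, Ndrg2 its exon of 42 nt in 28.5% and 31.0%, and Tpm3 its exon of 79 nt in 6.53% and 6.79%. Of 7112 annotated cassette exons with at least 20 informative reads in each library, 1931 (27.2%) were included in 5 to 95% of reads in both (771 with annotated models only and 1248 with at least 50 reads). Over these 1931 exons inclusion correlated at r = 0.966, with a median absolute difference of 4.00 percentage points. Over all 7112 exons, most of them near 0 or 100%, r was 0.995.

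The two-sided Fisher exact test called 24 of the 7112 exons between the libraries, 12 of them by at least 10 percentage points. In the isoform list, the exon of 30 nt in Ppp3ca (chromosome 3, 136932011 to 136932040) was included in 72.5% (exact 95% interval 71.6 to 73.4) and 62.4% (60.8 to 64.0; exact adjusted p = 1.34e-24). The exon of 63 nt in the NMDA receptor gene Grin1 was included in 15.2% and 29.0% (exact adjusted p = 0.000108), that of 93 nt in Bin1 in 67.9% and 56.8%, that of 168 nt in Aplp2 in 77.3% and 69.2% and that of 39 nt in Ndrg4 in 91.5% and 93.6%. The exon of 36 nt in Aplp2, at 78.2% and 84.0%, did not pass. Outside that list the largest differences were in Car12 (30 nt, 59.0% and 3.33%), Enpp2 (75 nt, 6.97% and 34.3%), Aen (601 nt, 66.7% and 45.3%), Sdr39u1 (83 nt, 66.9% and 85.2%) and Rps6kb1 (115 nt, 38.2% and 23.3%). Inclusion of the shortest exons was near 0, with a median of 0% over 94 exons of up to 18 nt and 59.3% and 65.8% over 123 exons of 19 to 27 nt. Abi1 included an exon of 15 nt in 99.8% and 99.6% and Mef2c one of 24 nt in 95.9% and 92.6%, while Nsmf (6 nt), Apbb1 (6 nt) and Ewsr1 (18 nt) had 0%.

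**Figure D5:**
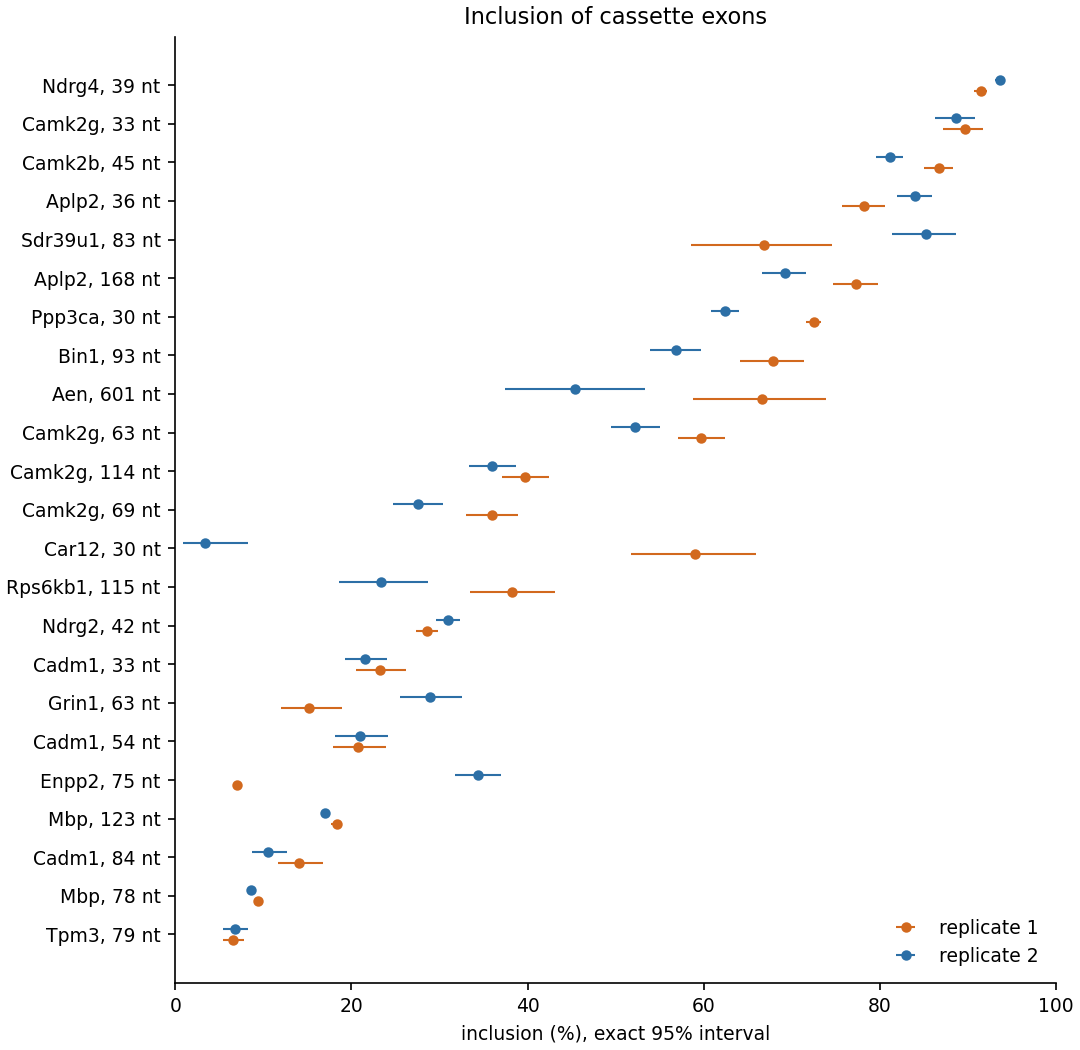
Inclusion (%, horizontal axis) of cassette exons named by gene and length in replicate 1 (orange) and replicate 2 (blue), with exact 95% intervals from counting. Most pairs lie close together, while the 30 nt exon of Car12 lies at 59.0% and 3.33% and the 75 nt exon of Enpp2 at 6.97% and 34.3%.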

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

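The number of spike-in reads was counted as planned, and no test was chosen after seeing it. Reads of ERCC and SIRV control RNAs numbered 1448 in replicate 1 (599 ERCC and 849 SIRV) and 836 in replicate 2 (438 and 398), 0.0506% and 0.0278% of all reads. Both exceed the limit of 3 reads, and they were not used for scaling.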

How the results depend on the processing

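The alternatives with length centring, with exons of 19 nt or longer and without models a very short exon or intron away from the annotation were chosen after seeing the results. The replicate correlation (r = 0.960) was 0.965 with a pseudocount of 10, 0.930 for genes with at least 10 reads and 0.950 with annotated models only. Genes differing between the libraries fell from 4855 to 2338 by an exact negative binomial test with an assumed variation of 0.1, and to 1790 with a 2-fold minimum. The median summed CPM of a list was 357 with annotated models only against 429. With annotated models only, 18 list sums moved by more than their SD and 11 did not. Likewise 12 CPM values of the highest genes moved and 8 did not. Of the named leading isoform shares 11 moved and 22 did not, and of the named inclusion values 12 moved and 10 did not. With ISM models, 16 leading shares moved and 22 did not. Genes using more than 1 isoform numbered 1373 with the second at 20% or more, against 2478. Genes with differing isoform usage numbered 379 with ISM models and 105 with a minimum of 10 percentage points, against 163. Genes led by an unannotated model numbered 499 without replicate 2 and 544 without replicate 1, against 348. Cassette exons between 5 and 95% numbered 771 with annotated models only and 1248 with at least 50 reads, against 1931. With only models of at least 2 reads, the mean share was 6.04% against 6.80% for NIC, 2.43% against 3.69% for NNC and 0.239% against 0.336% for intergenic models. The choroid plexus shift ran from -1.40 with a pseudocount of 10 to -3.46. Length centring put the dentate granule (0.76), immediate early (-0.50) and thalamus (0.53) lists outside the random range, as a minimum of 50 reads did for thalamus (1.12). The lists outside the range kept their direction. Inside it, length centring turned the medians for postsynaptic genes (-0.13 to 0.08) and meningeal fibroblasts (-0.01 to 0.05), and a minimum of 50 reads those for CA2 (0.04 to -0.26), heat shock (0.15 to -0.06), striatum (0.10 to -0.04) and meningeal fibroblasts (0.59). The meningeal median also turned with a pseudocount of 10 (0.01), and the synaptic vesicle median, at 0.00, with TMM scaling. No paired analysis was possible because there was 1 group.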

Other observations

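The protein forms, the second choroid plexus list, the length tests and the test of short exons below were chosen after seeing the results. The outcome expected of each explanation was written before its test, except for length centring and for pairs with the same outermost splice sites. With 1 group, no biological explanation was tested. Isoforms were grouped by the protein they encode for genes of synapses, with P values adjusted over these 8 tests alone. The flop form, 1 of 2 alternative exon choices of AMPA receptors, made up 70.2% and 73.1% of classed reads for Gria1 and 64.2% and 67.3% for Gria2 in replicates 1 and 2, while Gria3 was nearly all flip (97.9% and 96.9%). Snap25 gave SNAP25b, the adult form, in 91.5% and 94.8% (Fisher exact adjusted p = 3.20e-27). Mapt, which encodes tau, gave the 4-repeat form in 127 of 129 and 471 of 471 classed reads, and App the form without the Kunitz domain in 93.6% and 95.1%. The N1 cassette of Grin1 was present in 57 of 357 and 171 of 596 classed reads (Fisher exact adjusted p = 2.85e-05).

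Among genes annotated as non-coding, 2900097C17Rik (1121 reads in each library) and the imprinted Meg3 (518 and 553) were close between the libraries, and Malat1, a nuclear RNA, had 114 and 228. Higher in replicate 1 were Gm15337 (474 and 279), 2310075C17Rik (460 and 122), Gm26694 (287 and 28), Gm47163 (270 and 71) and Gm26724 (203 and 119). BC065397 (254 and 391) and B230209E15Rik (118 and 191) were higher in replicate 2. Cct6a, a chaperonin subunit, carries a non-coding class in this annotation and had 466 ± 0.818 CPM (SD, n = 2). The processed pseudogenes Gm12033 (367 and 1881), Gm5559 (370 and 1650) and Gm13394 (72 and 307) were higher in replicate 2, where their reads have not been separated from those of their parent genes. The annotation writes the frameshift of Oaz1 and Oaz2 as a gap of 1 nt, so reads through it are called NIC.

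The choroid plexus list was far higher in replicate 1. After centring on transcript length its median was still -3.15 (percentile 0, 8 genes), which argues against the length trend as the cause. A second list of 14 choroid plexus markers had a median of -2.29 (percentile 0), and all 9 tested members, such as Slc13a4 (57 and 12 reads), Steap1 (44 and 4) and Cldn2 (26 and 1), were higher in replicate 1. A larger share of choroid plexus tissue in replicate 1 could give this, but no count of cells was made here. Enpp2 is also made by oligodendrocytes, of whose 12 markers 7 were higher in replicate 2 and 1, Trf, in replicate 1.

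Short transcripts were higher in replicate 2, and without 197 genes of the classes known for short mRNAs the correlation of log2 ratio with length was -0.303 over 8898 genes, against -0.317 over 9095, so these classes alone do not explain it. Within genes, the shorter less the longer of 2 annotated isoforms gave a median of -0.0366 (-0.0859 to 0.0218; 487 of 1020 positive, exact sign test p = 0.159). Recovery by annotated isoform length had been set beforehand to give a median above 0, so this result went against it. Annotated models carry annotated ends whatever the ends of the reads, so recovery by the length of the reads was left undecided. The next test was added afterwards. Pairs with the same outermost splice sites gave 0.216 (0.0262 to 0.459; 70 of 115, exact sign test p = 0.0248) when they differed by at least 500 nt, but 0.0851 at 300 nt (exact p = 0.209), 0.0434 at 200 nt (exact p = 0.465) and 0.0207 at 100 nt (exact p = 0.484). Pairs whose leading model is under 2200 nt, where the trend lies, gave 0.630, 0.412, 0.299 and 0.169 at these limits (exact p = 0.000156, 0.00109, 0.00446 and 0.00335). Recovery by length could give this, though all pairs passed at 500 nt only. The limit of 2200 nt was taken from the trend in the same data, the sets of pairs overlap, and 1 gene can give several pairs. These values therefore do not decide the question. RNA input differed as well, with 1 library at each amount, so the causes cannot be told apart.

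Of 94 cassette exons of up to 18 nt, 71 (75.5%) had 0% inclusion in both libraries. Of 18 exons of this size that no annotated transcript skips, 13 were skipped in over 50% of reads. An exon of Nudt5 is counted among them in forms of both 9 and 10 nt, with the same skipping reads. The median skipped share of the 18 was 100%, against a median of 0% over 29855 exons of 28 to 120 nt. In Hnrnpk the exon of 16 nt was absent from all 5203 and 3700 reads, and Uchl1, a neuronal ubiquitin hydrolase, lacked 1 of 12 nt, while the 5 exons of 17 or 18 nt, in Sptan1, Sugt1, Ptprb, Atp2a2 and Syt17, were kept. Failure of the alignment to place exons of 16 nt or less could explain this, although not every such exon was lost. Abi1 kept a cassette exon of 15 nt in 99.8% and 99.6% of reads, and Sptan1 kept one of 15 nt in 98.4% and 99.2%. Such a failure would also make the unannotated leading models of Hnrnpk and Sept7 products of the method. Inclusion values for exons of this size are therefore uncertain.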
